A study of Homo sapiens with 60 samples.

How the data were processed

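HT29, an established human colorectal adenocarcinoma cell line, was treated for 24 h with ethanol extracts of 4 herbs and 4 herbal formulas. Per the labels' protocols, mRNA libraries were made from total RNA with an integrity number above 7 with a directional MGIEasy kit and sequenced on an MGI instrument as 100 bp paired-end reads. Per the series' design text, cells received each extract at 3 doses, the high dose being the IC20 where that lay below 500 µg/mL, and 1/5 and 1/25 dilutions of it. Per the same text, samples without results because of low RNA concentration were excluded, and the groups held here have 1, 2 or 3 libraries. The vehicle is labelled 0.1% DMSO in the sample labels and 2% in the series' design text, so its concentration stays open. A wortmannin control that the design text names was not analysed here. The labels do not say whether replicates were separate cultures, so p-values measure the spread between these libraries, which may be technical.

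The deposited table holds expected counts per gene, which the authors estimated with RSEM 1.3.3 after FastQC 0.11.9, Trim Galore 0.6.5 and STAR 2.7.3a against hg38 (GRCh38), per the submitters' processing notes. The annotation release and the strand setting of the counting are not given in the sources used here. Of the values, 10.0% were not exactly whole numbers (no tolerance), and all were rounded to whole counts before testing. The table has 60675 genes, 56558 of which matched a symbol in the gene name table. Coordinates and gene types come from GENCODE 29 on GRCh38, which holds 57055 of the genes (94.0%), and are given 1-based. All columns matched a sample label. Without a stated strand setting, reads of a gene and of its antisense partner cannot be told apart with certainty, and RSEM can divide reads among near-identical copies, so values of antisense genes, pseudogenes, readthrough genes and close families such as AKR1C or CYP4F are uncertain to that extent.

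Genes were tested with edgeR 4.0.16 in R 4.3.3: TMM factors, filterByExpr by group, a quasi-likelihood fit with 1 coefficient per group and a two-sided quasi-likelihood F-test, with Benjamini-Hochberg adjustment over all 17092 genes kept. Adjusted p in the text is this value, and a gene is called at adjusted p under 0.05. The fit took 57 libraries, the vehicle and the 21 extract-by-dose groups with 2 or 3 libraries, which share 1 estimate of the spread on 35 residual degrees of freedom. The standard error (SE) of a log2 fold change was its size divided by the square root of F. Levels are in CPM (depth-scaled counts, cpm of edgeR), computed from the rounded counts and TMM-scaled totals. Each dose was compared with the vehicle, the high dose with the low dose, and 3 pairs of extracts whose library names begin with the same set number with each other at high dose. All comparisons with the vehicle share its 3 libraries, too few to divide into parts of 2, so those comparisons share chance values. Unchanged groups were simulated 20 times for the low-dose overlap and for the similarity with high minus vehicle. The list tests of the extracts were not set against such simulations. High against low and the direct comparisons use no vehicle library. The vehicle libraries have a name prefix of their own and share no set number with any extract. Comparisons with the vehicle thus cannot separate an extract effect from a difference between sets.

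The library labelled Saposhnikoviae Radix low replicate 2 stood apart from all others. It enters the fit of 57 libraries as planned, and a fit of 56 libraries without it was added after it was seen. That fit kept 16978 genes with 34 residual degrees of freedom, and its negative binomial dispersion was 0.00272 against 0.0269 with the library, so counts from both fits are printed side by side.

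The gene lists, the rule for named genes, the tests and the alternatives below were fixed before the data were examined. Exceptions are the fit of 56 libraries and those checks of the outlying library that the flagged results name as chosen later. The lists were AHR targets, NRF2 targets, PXR and CAR targets, integrated stress response, ER chaperones, heat shock, cholesterol synthesis, fatty acid synthesis, PPAR targets, cell division, DNA replication, p53 targets, NF-kB and chemokines, interferon response, metallothioneins, hypoxia and glycolysis, MAPK output, WNT targets, enterocyte, goblet cell and mucus, autophagy and lysosome, ribosome biogenesis, mitochondrial transcripts, cytosolic ribosomal proteins, and markers of fibroblasts, blood cells and hepatocytes. Each list with at least 5 tested members was tested at high dose against the vehicle with camera (limma 3.58.1), a two-sided competitive test with the inter-gene correlation estimated per list, adjusted with Benjamini-Hochberg over all lists and 7 extracts. Some genes stand in more than 1 list, such as SLC7A11 and NQO1. Named genes for each extract at high dose were the 12 largest rises and 12 largest falls among genes with a symbol, adjusted p under 0.05, a mean of at least 5 CPM in 1 of both groups and no overlap between the groups' libraries. For high against low and the direct comparisons they were the 5 and 5 by the same rule, and for each list up to 4 members with the smallest adjusted p.

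Okbyeongpung-san has 1 library per dose and no test. Its log2 CPM (prior count 2) was set against the mean of the vehicle libraries, list medians were placed among 10000 random lists matched on mean expression, and the 10 highest and 10 lowest ratios among genes of at least 10 CPM in 1 of both are named. Similarity between a formula and a herb was the Pearson correlation across genes of high-minus-low log2 changes, and the mean over the 4 pairs in which the herb is a constituent was set against all 576 relabelings of herbs and formulas in an exact one-sided permutation test.

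Alternatives were DESeq2's median-of-ratios factors in edgeR (called RLE here), no low-count filter, a DESeq2 1.42.0 Wald test, the replicate number as a block, a fit of only the libraries compared and the vehicle, and each library left out in turn. For lists they were a preset inter-gene correlation of 0.01, fry, and high against low. For the similarity they were Spearman correlation, a minimum of 10 CPM, a prior count of 0.5 and high minus vehicle, and for Okbyeongpung-san its own low-dose library as the reference. The pipeline was tested on counts simulated for Menthae Herba high against vehicle with 200 changed genes. With the spread of the 57 libraries (16816 genes), 62 of 100 genes changed by 1.5-fold and 83 of 100 changed by 2-fold were called, and 7 unchanged genes. With the spread of the 56 libraries (16643 genes), 98 of 100, 100 of 100 and 16 were called. The limit on unchanged genes was first set at 0.1 of the 2-fold genes called, which these 16 exceeded, and it was reset after that result to 0.1 of all changed genes called, which they meet. Calls of the smaller fit thus held more unchanged genes in this simulation than the 0.05 level allows for. A list shifted by 0.5 on the log2 scale was recovered in both, and in a draw without that shift 0 of 25 lists were called. Genes were drawn independently, so that 0 says little about false list calls where the genes of a list vary together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.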

Results

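HT29 cells, a human line from a colorectal adenocarcinoma that keeps features of mucus-secreting and absorptive gut epithelium, were profiled by RNA-seq after 24 h with an herbal ethanol extract or DMSO. The 60 libraries fall into 25 groups: 3 vehicle libraries and 8 extracts at a high, a medium and a low dose. The herbs Menthae Herba and Saposhnikoviae Radix and the formulas Saengmaek-san and Guibi-tang have 3 libraries per dose at 500, 100 and 20 µg/mL. The herbs Polygalae Radix (380, 76 and 15.2 µg/mL) and Aucklandiae Radix (370, 74 and 14.8 µg/mL) and the formula Soyo-san (500, 100 and 20 µg/mL) have 2 per dose. Okbyeongpung-san has 1 library at each of 500, 100 and 20 µg/mL. Total expected counts per library ranged from 17079221 to 36796414. The series asks how herbal formulas and their constituent herbs act on the transcriptome. It is not stated whether replicates were separate cultures, so the p-values below measure the spread between these libraries.

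One library, Saposhnikoviae Radix low replicate 2, stood apart from the other 59. Its highest correlation with a library of its own group was 0.832, against at least 0.989 for every other library with a group mate. Mitochondrial genes took 3.33% of its counts, against 6.19% to 12.3% in the others, and genes annotated as antisense took 1.16%, against 0.306% to 0.388%. It has the lowest total of all libraries, 17079221, and the next lowest has 18690501. Because all groups share 1 estimate of the spread, this library widens it for every comparison, and counts are given with it (57 libraries in the fit) and without it (56 libraries).

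**Figure D1:**
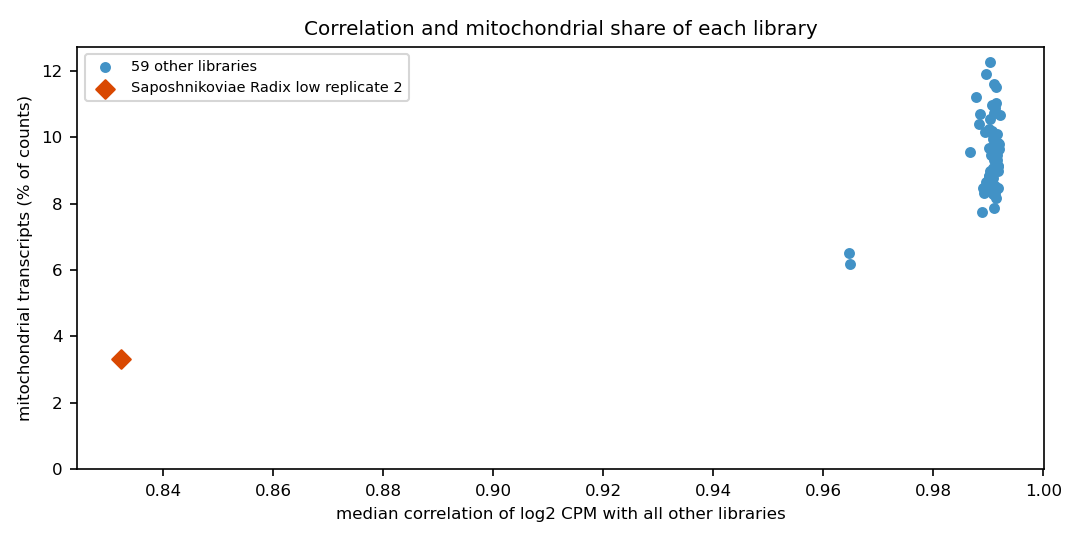
Each point is 1 of the 60 libraries, with its median correlation with all other libraries (x, log2 CPM) and its share of mitochondrial counts (y, %). Saposhnikoviae Radix low replicate 2 (diamond) lies at 0.832 and 3.33%, and the next lowest correlation is 0.965, in Aucklandiae Radix high replicate 2.

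The first question was how many genes differ from the vehicle at each dose. At high dose 6886 genes differed for Aucklandiae Radix, 1937 for Polygalae Radix, 1106 for Guibi-tang, 1071 for Menthae Herba, 157 for Soyo-san, 78 for Saengmaek-san and 53 for Saposhnikoviae Radix (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Without the outlying library the same comparisons gave 10627, 6246, 5073, 4883, 3061, 2047 and 1781 genes. These high doses are not equivalent. By the rule of the design text Aucklandiae Radix (370 µg/mL) and Polygalae Radix (380 µg/mL) were at their IC20, and the others at the limit of 500 µg/mL. At medium dose the counts were 161 for Aucklandiae Radix, 144 for Polygalae Radix, 19 for Menthae Herba, 17 for Saposhnikoviae Radix, 38 for Saengmaek-san, 31 for Guibi-tang and 24 for Soyo-san, and without the outlying library 2358, 1763, 1783, 644, 1988, 1915 and 1467. At low dose they were 1 for both Polygalae Radix and Aucklandiae Radix, 22 for Menthae Herba, 96 for Saengmaek-san, 13 for Guibi-tang and 12 for Soyo-san. The 4721 genes of Saposhnikoviae Radix low rest on the outlying library: without it 1993 genes differed, of which 575 were called in both fits in the same direction, and without replicate 1 or replicate 3 the count was 8584 or 8788. Without the outlying library, the low-dose counts of the other extracts were 849 to 3124. Each medium- and low-dose count of the fit of 57 libraries moved beyond 1.5 times with some library left out, such as Saengmaek-san low from 96 to 11. Another split of the same libraries called more genes than the real one for Saposhnikoviae Radix medium (66 against 17) and Guibi-tang low (22 against 13).

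**Figure D2:**
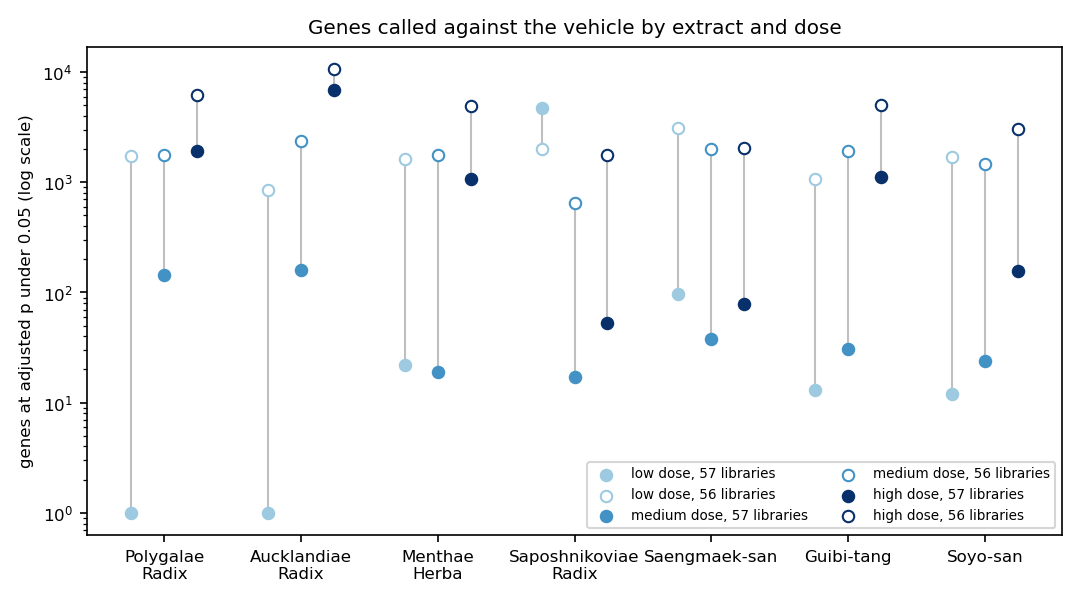
Number of genes called against the vehicle (y, log scale) for the 7 extracts with replicates (x), coloured by dose, in the fit of 57 libraries (filled) and in the fit without the outlying library (open). Aucklandiae Radix high has the most calls in both, 6886 and 10627.

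Aucklandiae Radix at high dose gave the widest change, with oxidative-stress and lysosomal genes rising and replication and mitotic genes falling. AHNAK2, a giant scaffold protein under the plasma membrane (ENSG00000185567, GRCh38 chromosome 14, 104937244 to 104978357), rose from 7.41 ± 0.892 CPM (SD, n = 3) to 468 ± 40 CPM (n = 2), a 62.8-fold change (log2 5.97 ± 0.18 SE, adjusted p 2.11e-26, edgeR quasi-likelihood test with Benjamini-Hochberg). SDCBP2, a syntenin that binds membrane phospholipids, rose by 4.84 (log2) from 6.52 to 187 CPM. The fatty acid hydroxylase gene CYP4F11 rose by 5.48, from 0.973 to 42.8 CPM, and DHRS9, a retinol dehydrogenase, rose by 5.54, from 0.653 to 31.9 CPM. CST1, which encodes a secreted inhibitor of cysteine proteases, rose by 5.97. The squamous envelope gene SPRR1B was also among the 12 largest rises. The long non-coding RNA LINC00261 (ENSG00000259974, chromosome 20, 22547671 to 22578642) fell by 6.26 ± 0.31 SE (log2), from 15.5 ± 0.334 to 0.199 ± 0.0243 CPM, 76.9 times lower (adjusted p 1.67e-19). The epithelial NADPH oxidase NOX1 fell by 4.70, and SLITRK6, a neurite-growth membrane protein, by 4.10, from 67.3 to 3.93 CPM.

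Of the Aucklandiae Radix calls 3399 rose and 3487 fell, and 1212 and 1572 of these changed by at least 2-fold. In the NRF2 list, target genes of the main oxidative-stress regulator, 22 rose, 0 fell and 2 did not pass, with a median of 1.47 (camera adjusted p 4.05e-10), and 22 rose when adjusted over the list alone. Among its members were AKR1C1, an aldo-keto reductase (3.57 ± 0.18 SE), HMOX1, which degrades heme (2.35 ± 0.12), and GCLM, a subunit of the enzyme that limits glutathione synthesis (1.81 ± 0.10). In the autophagy and lysosome list 20 rose and 4 did not pass (median 0.87, adjusted p 6.7e-08; 20 rose and 1 fell adjusted over the list alone), including the autophagy receptor SQSTM1 (2.25 ± 0.06), the protease CTSL (3.71 ± 0.14) and the galactosidase GLA (2.18). The hypoxia and glycolysis list had 15 rises, 2 falls and 5 not passed (median 0.81, adjusted p 0.00233; 15 and 2 adjusted over the list alone), with the stress gene NDRG1 at 3.33 and the glucose transporter SLC2A1 at 2.23. In the NF-kB and chemokine list 9 rose, 1 fell and 6 did not pass (median 0.79, adjusted p 0.00398; 9 and 2 adjusted over the list alone), among them the apoptosis inhibitor BIRC3 (3.04) and TNFAIP3, which ends NF-kB signalling (2.00). The ER chaperone list had 12 rises and 8 not passed (median 0.62, adjusted p 0.0144; 12 rose adjusted over the list alone), with the co-chaperone DNAJB9 at 2.27 and HSPA5, the main chaperone of the ER, at 0.82. In the integrated stress response list 12 rose, 4 fell and 6 did not pass (median 0.56, adjusted p 0.0091; 13 and 4 adjusted over the list alone), with asparagine synthetase ASNS at 1.69 and the cystine transporter SLC7A11 at 2.20, but without the outlying library this list did not pass (adjusted p 0.0732).

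Genes of DNA copying and mitosis were lower after Aucklandiae Radix high. In the DNA replication list 0 rose, 20 fell and 5 did not pass (median -0.92, camera adjusted p 0.000454; 21 fell adjusted over the list alone), with the helicase subunits MCM5 at -1.11 and CDC45 at -0.75 and the ribonucleotide reductase subunit RRM1 at -1.34. In the cell division list 24 fell and 1 did not pass (median -0.92; 24 fell adjusted over the list alone), with the mitotic cyclin CCNB2 at -1.26 and the kinase AURKB at -1.47. Its adjusted p of 0.0383 was 0.0531 without Aucklandiae Radix high replicate 2 and 0.0582 without replicate 3. The WNT target list had 1 rise, 8 falls and 8 not passed (median -0.51, adjusted p 0.0262, 0.0538 without the outlying library; 1 and 8 adjusted over the list alone), with the intestinal stem-cell receptor LGR5 at -3.81 and the crypt receptor EPHB3 at -2.30. Among goblet cell and mucus genes 2 rose, 10 fell and 8 did not pass (median -0.88, adjusted p 0.00986, 0.125 without the outlying library; 2 and 10 adjusted over the list alone), including AGR2, which folds mucins (-1.06), and its paralog AGR3 (-2.98). In cholesterol synthesis 1 rose, 11 fell and 13 did not pass (median -0.35, adjusted p 0.0244; 1 and 11 adjusted over the list alone), with the thiolase ACAT2 at -1.18 and DHCR7, which makes cholesterol from its last precursor, at -0.64.

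Against its own low dose, a comparison free of vehicle libraries, Aucklandiae Radix high had 3006 genes higher and 3274 lower (6280 in all, 10030 without the outlying library). AHNAK2 rose by 6.07 and DHRS9 by 6.19, while LINC00261 fell by 6.16, the extracellular protease ADAMTS6 fell by 5.04 and NOX1 fell by 4.92 (log2). Leaving out any 1 library of the groups compared gave 5182 to 6416 genes against the vehicle and 4850 to 4973 against the low dose.

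Polygalae Radix at high dose lowered chaperone genes and genes of the integrated stress response against the vehicle. The autophagy and lysosome list did not pass, with 2 rises, 1 fall and 21 not passed (median 0.02, camera adjusted p 0.132). ASNS, which makes asparagine (ENSG00000070669, chromosome 7, 97852118 to 97872542), fell from 54.8 ± 2.93 CPM (SD, n = 3) to 19.1 ± 2.03 CPM (n = 2), a log2 change of -1.52 ± 0.08 SE (adjusted p 1.44e-17, edgeR quasi-likelihood test with Benjamini-Hochberg). PHGDH, the entry enzyme of serine synthesis, fell by 1.75, from 31.6 to 9.36 CPM. VIL1, the actin-bundling villin of the brush border, fell by 1.59, and the retinal dehydrogenase ALDH1A1 by 1.60. HADHA, part of the mitochondrial trifunctional protein of fatty acid oxidation, fell by 1.38. SQSTM1 rose by 1.25 ± 0.06 SE (log2), from 364 ± 18.9 to 867 ± 53.1 CPM (adjusted p 1.8e-18). FLCN and FNIP1, partners in the folliculin complex that controls lysosomal signalling, rose by 1.22 and 1.24, and NEAT1, the RNA scaffold of paraspeckles, rose by 1.34.

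For Polygalae Radix 687 genes rose and 1250 fell, 82 and 208 of them by at least 2-fold. In the heat shock list 0 rose, 10 fell and 8 did not pass (median -0.62, camera adjusted p 0.00021; 13 fell adjusted over the list alone), with the chaperones HSP90AB1 at -0.92, HSPD1 at -0.73 and HSPA8 at -0.69. The hypoxia and glycolysis list had 8 falls and 14 not passed (median -0.25, adjusted p 0.00534; 1 rose and 9 fell adjusted over the list alone), with the glycolytic enzymes PGK1 at -1.07, LDHA at -1.11 and ENO1 at -1.11. Of the PPAR targets, genes of fat oxidation and storage, 1 rose, 6 fell and 8 did not pass (median -0.32, adjusted p 0.0035; 1 and 7 adjusted over the list alone), with HADHA, a subunit of the mitochondrial enzyme for long-chain fat oxidation, at -1.38. ER chaperones (8 fell, 12 not passed, median -0.28, adjusted p 0.0085; 8 fell adjusted over the list alone) included HSPA5 at -0.77 and HSP90B1 at -0.82. The integrated stress response list had 3 rises, 9 falls and 10 not passed (median -0.24, adjusted p 0.0126; 3 and 9 adjusted over the list alone), with the serine and one-carbon enzymes SHMT2 at -1.13 and PCK2, a mitochondrial carboxykinase, at -0.94. WNT targets (6 fell, 11 not passed, median -0.50, adjusted p 0.0147; 1 rose and 6 fell adjusted over the list alone) included the crypt receptors EPHB3 at -0.97 and EPHB2 at -0.91. Of 6 blood cell markers 3 fell and 3 did not pass (median -0.60, adjusted p 0.0161; 4 fell adjusted over the list alone), with lysozyme LYZ at -0.60, a gene this line expresses at 1489 CPM in the vehicle. The ER chaperone, integrated stress response, WNT and blood cell lists did not pass between high and low dose (adjusted p 0.0622, 0.0913, 0.0616 and 0.0583; 0.0866, 0.149, 0.0425 and 0.0484 without the outlying library), and the blood cell list did not pass without the low-count filter (0.0562). The heat shock list passed between doses with all 57 libraries (median -0.32, 0.0401) but not without the outlying library (0.0646). The NRF2 list moved both ways, with 8 rises, 7 falls and 9 not passed (adjusted p 0.862).

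Between high and low dose of Polygalae Radix 505 genes were higher and 1005 lower (1510 in all). GDF15, a stress cytokine, rose by 1.28, from 45.1 to 110 CPM, and the phosphatase DUSP5 by 1.29, while PHGDH fell by 1.66 and VIL1 by 1.59 (log2). Both counts fell whichever Polygalae Radix library was left out, which leaves 1 library in its group and less power, so they single out no library. The count of 1937 against the vehicle was 1155 without Polygalae Radix high replicate 2 and 928 without replicate 3. Against the low dose it was 767 without high replicate 2, 903 without high replicate 3, 971 without low replicate 2 and 839 without low replicate 3.

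Polygalae Radix and Aucklandiae Radix at high dose, whose libraries belong to the same set, were compared directly. LINC00261 was higher in Polygalae Radix by 6.06 (log2), 13.5 against 0.199 CPM, and NR0B2, a nuclear receptor that represses bile acid synthesis, by 4.93 ± 0.27 SE, 12.1 against 0.387 CPM (adjusted p 6.26e-18, edgeR quasi-likelihood test with Benjamini-Hochberg). CST1 was lower in Polygalae Radix, with a difference of -6.62, and NAV3, a microtubule-binding protein, with -6.07. In all 3023 genes were higher and 3174 lower in Polygalae Radix (6197, and 9952 without the outlying library). Among genes with a symbol, a mean of at least 5 CPM and a called direct difference, 342 were called in opposite directions against the vehicle by both extracts. Leaving out 1 library gave 4707 to 4908 genes.

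Menthae Herba at high dose raised xenobiotic and oxidative-stress genes and lowered mucus genes. CYP1A1, the cytochrome P450 most tightly driven by the aryl hydrocarbon receptor AHR (ENSG00000140465, chromosome 15, 74719542 to 74725610), rose 11.3-fold, from 0.659 ± 0.0646 to 7.5 ± 1.06 CPM (SD, n = 3 each; log2 3.50 ± 0.21 SE, adjusted p 4.97e-15, edgeR quasi-likelihood test with Benjamini-Hochberg). SLC7A11, the cystine and glutamate antiporter, rose by 1.32, from 109 to 272 CPM (167 at low dose), AKR1B10, a reductase of aldehydes, by 1.24, and the aldehyde dehydrogenase ALDH3A1 by 1.21. FCGBP, a mucus protein that binds IgG, fell by 1.99 ± 0.16 SE (log2), from 15.6 ± 3.75 to 3.91 ± 0.163 CPM (adjusted p 1.73e-11). The gel-forming mucins MUC2 and MUC5AC fell by 1.82 and 1.40, NOX1 by 1.51, and the Notch ligand DLL4 by 1.48.

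For Menthae Herba 369 genes rose and 702 fell, 27 and 147 by at least 2-fold. In the NRF2 list 17 rose, 0 fell and 7 did not pass (median 0.52, camera adjusted p 4.57e-13; 20 rose adjusted over the list alone), with GCLM at 1.16 and HMOX1 at 1.04. The AHR list had 4 rises and 4 not passed (median 0.72, adjusted p 7.06e-07; 5 rose adjusted over the list alone), with CYP1B1, a P450 that hydroxylates estrogens, at 0.90 and the quinone reductase NQO1 at 0.57. Of the goblet cell and mucus genes 0 rose, 10 fell and 10 did not pass (median -0.81, adjusted p 5.12e-08; 1 rose and 12 fell adjusted over the list alone), with REG4, a secreted lectin, at -1.38 and AGR2 at -0.77. Cholesterol synthesis (5 fell, 20 not passed, median -0.22, adjusted p 7.28e-05; 6 fell adjusted over the list alone) included INSIG1, a sterol sensor, at -0.61 and the sterol cyclase LSS at -0.39. WNT targets (5 fell, 12 not passed, median -0.32, adjusted p 0.00181; 5 fell adjusted over the list alone) included EPHB3 at -1.04 and the WNT inhibitor NOTUM at -1.61. Ribosome biogenesis (4 rose, 19 not passed, median 0.25, adjusted p 4.5e-05; 6 rose adjusted over the list alone) included WDR43 at 0.43 and UTP20 at 0.54, both factors of the small subunit. DNA replication (1 rose, 24 not passed, median 0.21, adjusted p 0.00544) included CDC45 at 0.29, the single rise also when adjusted over the list alone. The integrated stress response list had 4 rises and 18 not passed (median 0.14, adjusted p 0.0144; 5 rose adjusted over the list alone). PPAR targets had 4 rises and 11 not passed (median 0.17, adjusted p 0.0262; 5 rose and 1 fell adjusted over the list alone), with the kinase PDK4, which limits glucose oxidation, at 0.65 and the lipid droplet gene PLIN2 at 0.54. The PPAR list did not pass without the outlying library (adjusted p 0.0674), without Vehicle replicate 1 (0.0583) or between high and low dose (0.0779).

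Against its low dose Menthae Herba high had 334 genes higher and 602 lower (936 in all), with CYP1A1 at 3.44, HMOX1 at 1.29, FCGBP at -2.19 and NOX1 at -1.70. The count against the vehicle, 1071, was 678 without Vehicle replicate 1, 665 without Menthae Herba high replicate 2 and 689 without replicate 3. The count against the low dose was 605 without high replicate 2, 590 without high replicate 3 and 621 without low replicate 2.

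At high dose of Saposhnikoviae Radix 53 genes differed from the vehicle, and 1781 without the outlying library, with AHR and NRF2 targets among the rises. Without that library only 49 genes differed from its own low dose, so the 1781 cannot be read as extract effects alone. CYP1B1 (ENSG00000138061, chromosome 2, 38066973 to 38109902) rose from 46.2 ± 1.03 to 94.8 ± 0.24 CPM (SD, n = 3 each; log2 1.04 ± 0.07 SE, adjusted p 8.09e-13, edgeR quasi-likelihood test with Benjamini-Hochberg). CYP1A1 rose by 2.44, SLC7A11 by 0.89, GCLM by 0.59, and RBL1, a retinoblastoma-like repressor of cell cycle genes, by 0.50. SLC7A11 was already at 188 and 160 CPM in low replicates 1 and 3, against 202 at high dose and 109 in the vehicle. BMP2, a secreted differentiation signal, fell by 0.61, the cell cycle inhibitor CDKN1A by 0.55 and the chaperone HSPA8 by 0.36. Fitted with the Saposhnikoviae Radix and vehicle libraries alone, the outlying one included, 7 of these genes had an adjusted p above 0.05, with CYP1B1 at 0.125, and CYP1A1 kept its call.

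Of the Saposhnikoviae Radix calls 22 rose and 31 fell. The AHR list had 2 rises and 6 not passed (median 0.36, camera adjusted p 4.08e-07; 3 rose adjusted over the list alone). In the NRF2 list 2 rose and 22 did not pass (median 0.13, adjusted p 5.85e-07; 6 rose adjusted over the list alone), and between high and low dose it did not pass (0.0564) but passed without the outlying library (median 0.18, 1.14e-07). The heat shock list had 3 falls and 15 not passed (median -0.25, adjusted p 0.00167; 1 rose and 5 fell adjusted over the list alone), but between high and low dose its median was 0.20 and it did not pass (0.352; 0.04 and 0.271 without the outlying library). Of the goblet cell and mucus genes 20 did not pass (median -0.17, adjusted p 0.0166; 2 fell adjusted over the list alone), and the list did not pass without the outlying library (0.0631), by fry (0.0508) or between high and low dose (0.335; 0.0344 without that library). The integrated stress response list had 1 rise, 1 fall and 20 not passed, the same adjusted over the list alone (median -0.16, adjusted p 0.0262), and it did not pass without the outlying library (0.0695), with RLE factors (0.0566) or between doses (0.329; 0.319 without it). Of the p53 targets 2 fell and 19 did not pass, also when adjusted over the list alone (median -0.07, adjusted p 0.0319), and between doses the list had 0.868 (0.0436 without the outlying library).

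Between high and low dose of Saposhnikoviae Radix 747 genes were higher and 3871 lower, a count that the outlying low-dose library makes. Without it 49 genes were called, 34 of them in both fits in the same direction. CYP1B1 was higher at high dose by 0.97 (log2), and by 0.84 without that library (adjusted p 8.07e-15). The AHR-induced gene TIPARP, an ADP-ribosyltransferase that restrains the receptor, was at 0.89, and at 0.38 without that library. The retinal dehydrogenase ALDH1A3 was at 1.04 and 0.58. CLVS1, CIDEB, IGSF6, TMEM266, GCOM1 and the readthrough genes COMMD3-BMI1 and ZFP91-CNTF, also among the 10 largest, lost their calls without it. TIPARP lost its call when any 1 of the 3 high-dose libraries was left out of the fit of 57. The count of 4618 rose to 9854 without low replicate 1 and to 9812 without low replicate 3. The high-dose count of 53 against the vehicle was 20 without Vehicle replicate 3, and 20, 12 and 19 without high replicates 1, 2 and 3.

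Menthae Herba and Saposhnikoviae Radix at high dose share a set and were compared directly. Relative to Saposhnikoviae Radix, Menthae Herba had higher CYP1A1 (1.06, 7.5 against 3.58 CPM), HMOX1 (0.92) and AKR1B10 (0.84 ± 0.10 SE, 260 ± 15.2 against 145 ± 1.58 CPM). It had lower FCGBP (-1.92), MUC5AC (-1.56) and MUC2 (-1.54). In all 134 genes were higher and 272 lower (406 by edgeR's quasi-likelihood test with Benjamini-Hochberg, and 2738 without the outlying library). The count was 231 and 211 without Menthae Herba high replicates 2 and 3, and 245, 239 and 243 without Saposhnikoviae Radix high replicates 1, 2 and 3.

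Guibi-tang, a formula that contains Polygalae Radix and Aucklandiae Radix, at high dose raised aldo-keto reductases and other NRF2 targets. AKR1B10 (ENSG00000198074, chromosome 7, 134527592 to 134541408) rose 3.78-fold, from 110 ± 1.7 to 414 ± 26.9 CPM (SD, n = 3 each; log2 1.92 ± 0.11 SE, adjusted p 5.87e-16, edgeR quasi-likelihood test with Benjamini-Hochberg). AKR1C2, a steroid reductase whose family members share much sequence, rose by 2.75, from 17 to 114 CPM, and AKR1C1 by 2.26. SLC7A11 rose by 1.70, ALDH3A1 by 1.74, AHNAK2 by 1.44 and SDCBP2 by 1.43, and the fatty acid hydroxylase paralogs CYP4F11 and CYP4F3 by 2.49 and 2.30. CD200, an immune-inhibiting surface protein, fell by 2.31, LINC00261 by 2.14, the Ras-like GTPase RASL11A by 1.63 and REG4 by 1.45.

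For Guibi-tang 498 genes rose and 608 fell, 81 and 116 by at least 2-fold. In the NRF2 list 23 rose and 1 did not pass, also when adjusted over the list alone (median 0.82, camera adjusted p 1.14e-16). The AHR list had 4 rises and 4 not passed (median 0.79, adjusted p 1.38e-07; 7 rose adjusted over the list alone), with CYP1A1 at 2.54 and CYP1B1 at 0.92. In cholesterol synthesis 6 fell and 19 did not pass (median -0.18, adjusted p 0.000361; 8 fell adjusted over the list alone), with the sterol cyclase LSS at -0.44. WNT targets (4 fell, 13 not passed, median -0.37, adjusted p 0.00107; 6 fell adjusted over the list alone) included EPHB3 at -0.93 and NOTUM at -1.23. Goblet cell and mucus genes (6 fell, 14 not passed, median -0.34, adjusted p 0.00118; 8 fell adjusted over the list alone) included AGR2 at -0.54 and REG4 at -1.45. The autophagy and lysosome list had 4 rises, 1 fall and 19 not passed, the same adjusted over the list alone (median 0.11, adjusted p 0.00172), with SQSTM1 at 0.64 and the lysosomal glycoprotein GPNMB at 1.85. Against its low dose Guibi-tang had 363 genes higher and 457 lower (820 in all), with AKR1C2 at 2.67 and CD200 at -2.22. The count against the vehicle, 1106, was 718 without Vehicle replicate 3 and 673 without Guibi-tang high replicate 3, and the count against the low dose stayed between 554 and 654 with 1 library left out.

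At high dose of Saengmaek-san 78 genes differed from the vehicle, and 2047 without the outlying library, with oxidative-stress and AHR targets among the rises. Without that library only 141 genes differed from its own low dose, so the 2047 cannot be read as extract effects alone. SLC7A11 rose from 109 ± 17.8 to 198 ± 17.6 CPM (SD, n = 3 each; log2 0.86 ± 0.13 SE, adjusted p 0.000656, edgeR quasi-likelihood test with Benjamini-Hochberg), and CYP1B1 rose by 0.62, from 46.2 to 70.7 CPM (adjusted p 3.58e-06). SLC7A11 was already at 172 CPM at low dose, and at 153 to 176 CPM at low dose of every extract. Most of its difference from the vehicle was thus there at the lowest dose, and an offset of the vehicle libraries stays open as the cause. GCLM rose by 0.65. REG4 fell by 0.70, EDN1, a vasoconstrictor peptide, by 0.61, AHDC1, a chromatin-associated protein, by 0.55, and EPHB3 by 0.48. In all 35 genes rose and 43 fell. The NRF2 list had 4 rises and 20 not passed (median 0.23, camera adjusted p 2.2e-08; 8 rose adjusted over the list alone), and the AHR list 2 rises and 6 not passed (median 0.30, adjusted p 8.99e-05; 3 rose adjusted over the list alone). Of the goblet cell and mucus genes 1 fell and 19 did not pass (median -0.27, adjusted p 0.00098; 3 fell adjusted over the list alone). Of the WNT targets EPHB3 alone fell, also when adjusted over the list alone, and 16 did not pass (median -0.14, adjusted p 0.00534). In the heat shock list 2 fell and 16 did not pass (median -0.19, adjusted p 0.0085; 1 rose and 4 fell adjusted over the list alone), with HSPA8 at -0.31, and between high and low dose its median was 0.06 and it did not pass (0.116). The PPAR list had 15 not passed (median 0.17, adjusted p 0.0109; 3 rose adjusted over the list alone), and the DNA replication list had 25 not passed and none adjusted over the list alone (median 0.13, adjusted p 0.0177, 0.0599 without Vehicle replicate 1).

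Against its low dose Saengmaek-san had 5 genes higher and 1 lower by edgeR's quasi-likelihood test (587 at unadjusted p under 0.05, and 141 called without the outlying library). AKR1B10 was higher by 0.64 and CYP1B1 by 0.52, and both kept their calls with any 1 library left out, when the count was 2 to 3. The 78 calls against the vehicle became 30, 128 and 22 without Vehicle replicates 1, 2 and 3, and 17 and 33 without Saengmaek-san high replicates 1 and 2.

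Saengmaek-san and Guibi-tang at high dose, from 1 set, were compared directly. Guibi-tang had the higher AKR1C2 (114 against 22.3 CPM; log2 Saengmaek-san minus Guibi-tang -2.36 ± 0.23 SE), AKR1C1 (-1.97) and SDCBP2 (-1.60). Saengmaek-san had the higher LINC00261 (1.59), RASL11A (1.38) and RARRES1, a retinoid-induced membrane protein (1.24). In all 233 genes were higher and 256 lower in Saengmaek-san (489 by edgeR's quasi-likelihood test, 2156 without the outlying library), and the count was 319 and 313 without Guibi-tang high replicates 2 and 3.

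Soyo-san, a formula that contains Menthae Herba, at high dose raised NRF2 targets. SLC7A11 (ENSG00000151012, chromosome 4, 138164097 to 138242349) rose from 109 ± 17.8 CPM (SD, n = 3) to 249 ± 3.66 CPM (n = 2; log2 1.19 ± 0.15 SE, adjusted p 5.14e-06, edgeR quasi-likelihood test with Benjamini-Hochberg), and it was at 167 CPM at low dose. AKR1C3 rose by 0.99, AKR1B10 by 0.88, GCLM by 0.86 and CYP1A1 by 2.08. ATP6V1B1, a subunit of the proton pump, fell by 0.88, EDN1 by 0.75 and CREB3L1, a membrane-bound transcription factor of secretory cells, by 0.69. In all 59 genes rose and 98 fell. The NRF2 list had 7 rises and 17 not passed (median 0.47, camera adjusted p 4.63e-12; 18 rose adjusted over the list alone), and the AHR list 3 rises and 5 not passed (median 0.47, adjusted p 8.61e-06; 4 rose adjusted over the list alone). Of the goblet cell and mucus genes 2 fell, also adjusted over the list alone, and 18 did not pass (median -0.28, adjusted p 0.013, 0.0585 without the outlying library and 0.0739 without Vehicle replicate 1). The PPAR list had 15 not passed (median 0.19, adjusted p 0.0157, 0.053 without Vehicle replicate 1; 2 rose adjusted over the list alone). In DNA replication 25 did not pass and 1 rose adjusted over the list alone (median 0.15, adjusted p 0.0389), and this list did not pass by fry (0.0508), between doses (0.0913) or without Vehicle replicate 1 (0.102). Against its low dose Soyo-san had 14 genes higher and 11 lower (25 by edgeR's quasi-likelihood test), with AKR1B10 at 0.97. That count was 6 and 94 without Soyo-san high replicates 1 and 2, and 3 and 2 without low replicates 1 and 2. The 157 calls against the vehicle became 48 without Vehicle replicate 3, and 16 and 102 without Soyo-san high replicates 1 and 2.

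Set side by side, 51 of the list-by-extract tests passed at high dose, 25 upward and 26 downward. All of them share the same vehicle libraries, and the agreement to be had between unchanged extracts was not simulated for lists. The NRF2 list rose in 6 of 7 extracts, with Polygalae Radix the exception, and its median ranged from 0.13 in Saposhnikoviae Radix to 1.47 in Aucklandiae Radix. AHR targets passed in 5, all but both herbs of the first set (Aucklandiae Radix 5 up and 1 down, adjusted p 0.102; Polygalae Radix 0 up and 2 down, 0.181). Some lists passed in none of the extracts in the fit of 57 libraries. For MAPK output, early targets of growth-factor signalling, the smallest adjusted p was 0.101, with 8 rises in Aucklandiae Radix such as FOSL1 at 2.13 and DUSP5 at 4.08. Enterocyte genes had 0.0816 (Polygalae Radix, VIL1 -1.59), interferon response 0.0762 (Menthae Herba and Guibi-tang, medians -0.25 and -0.29) and metallothioneins 0.105 (Guibi-tang, median -0.98). Hepatocyte markers had 0.113 (Menthae Herba), PXR and CAR targets 0.132 (Guibi-tang), mitochondrial transcripts 0.191 (Guibi-tang), fatty acid synthesis 0.511 (Polygalae Radix) and cytosolic ribosomal proteins 0.742 (Aucklandiae Radix). Without the outlying library some of these passed: enterocyte genes (0.00399) and fatty acid synthesis (0.0484) in Polygalae Radix, metallothioneins in Menthae Herba (0.0392) and Guibi-tang (0.027) and MAPK output in Saposhnikoviae Radix (0.0262) and Saengmaek-san (0.0413), all downward, and PXR and CAR targets in Guibi-tang (0.0442), upward. Fibroblast markers had 4 measured genes and were not tested. With the preset correlation of 0.01 the number of passing tests was 79, with fry 85 (49 of the 51 kept) and without the outlying library 60 (44 kept), and all 51 kept their calls at the preset value.

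**Figure D3:**
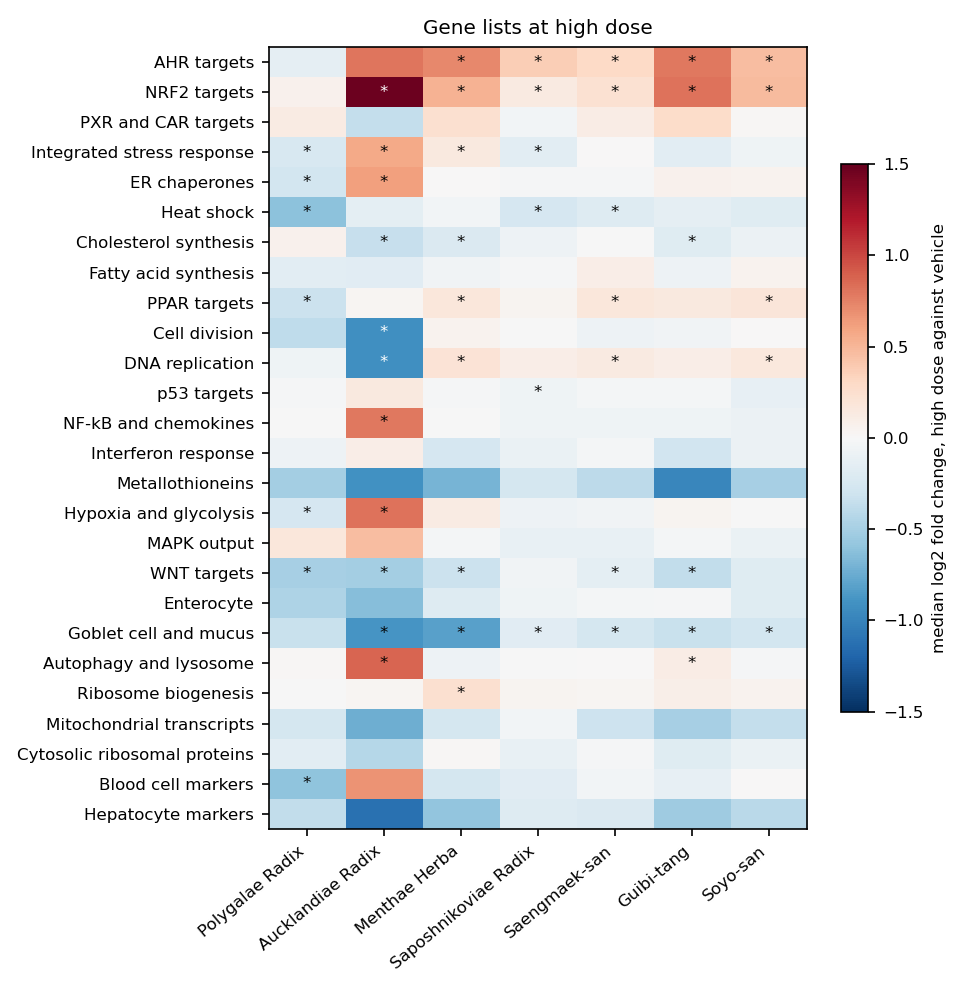
Median log2 fold change of each gene list at high dose against the vehicle (colour) by list (y) and extract (x), with asterisks where the list passed (camera, adjusted p under 0.05). The NRF2 list is marked in 6 of 7 extracts, and its highest median is 1.47 in Aucklandiae Radix.

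The dose series of single genes was read from group means. AKR1B10 had 110 CPM in the vehicle, 246 at medium and 224 at high dose of Aucklandiae Radix, 260 at high dose of Menthae Herba and 414 at high dose of Guibi-tang. SLC7A11 had 109 CPM in the vehicle and 153 to 176 CPM at low dose of the 8 extracts. Part of its difference from the vehicle was thus there at the lowest dose of every extract, and an offset of the vehicle libraries may be the cause. Doses were each tested against the vehicle and high against low, and a difference between medium and high was not tested.

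**Figure D4:**
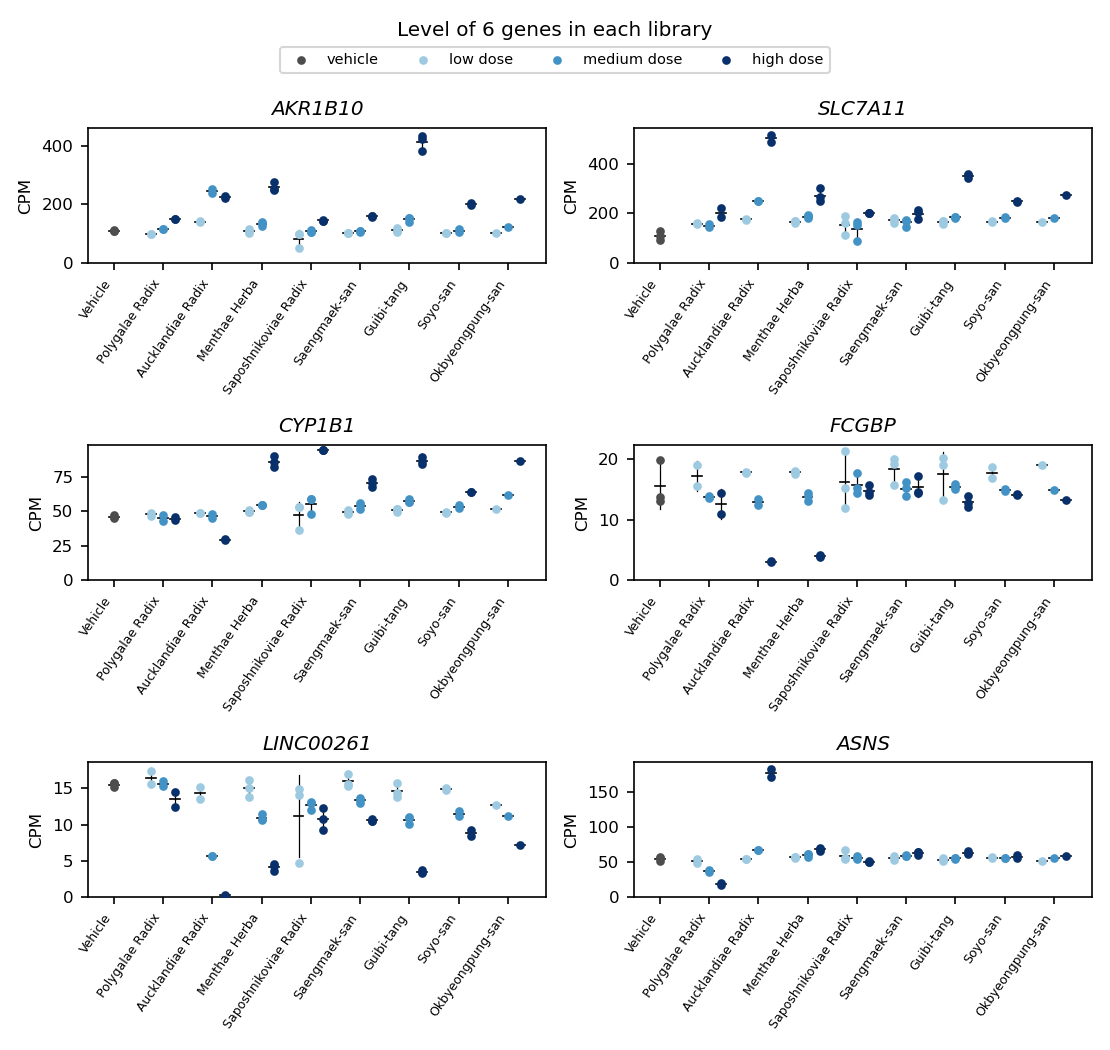
Levels (y, CPM, linear scale) of 6 genes in the vehicle and in each extract (x), coloured by dose. Points are libraries, short horizontal lines are group means and vertical lines are the mean ± SD. AKR1B10 has 110 CPM in the vehicle and 414 CPM in Guibi-tang high.

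The series pairs formulas with constituent herbs, so the similarity of their high-minus-low changes was tested. Across 18375 genes, which are not independent replicates, the 4 constituent pairs had a mean Pearson r of 0.2042 and the 12 other pairs 0.1175. The exact one-sided permutation p was 0.0764 over 576 relabelings. Several relabelings form the same 4 pairs, so the smallest permutation p possible is above 0.00174. Guibi-tang and Aucklandiae Radix had 0.4256, Soyo-san and Menthae Herba 0.2012, Guibi-tang and Polygalae Radix 0.1491, and Okbyeongpung-san and Saposhnikoviae Radix 0.0408, or 0.117 without the outlying library. The highest of the other pairs was Guibi-tang and Menthae Herba, at 0.3568. The test passed with Spearman correlation (0.2461, p 0.0278) and with a minimum of 10 CPM (0.3827, p 0.0139), and without the outlying library it had 0.2227 against 0.1325 (p 0.0556). It also passed with 1 library left out for Menthae Herba low replicate 1 (0.2076), Saengmaek-san low replicate 3 (0.204) and Soyo-san high replicate 1 (0.216). With high minus vehicle the means were 0.5093 and 0.4322 (exact permutation p 0.0833). Simulated unchanged groups that share the vehicle had a mean r of 0.3942. That r is no yardstick for changed extracts, whose own changes dilute it: Saengmaek-san and Aucklandiae Radix had 0.1719 against a simulated 0.417. The simulated mean covariance was 0.02876, and the observed ones were 0.04483 (that pair) to 0.1655 (Guibi-tang and Aucklandiae Radix). The simulation gave the vehicle no extra scatter.

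Okbyeongpung-san, a formula that contains Saposhnikoviae Radix, has 1 library per dose, so its values have no error and no test. At high dose NRF2 targets had a median of 0.51 above the vehicle mean (log2), with 22 of 24 above all 3 vehicle libraries, and AHR targets 0.61, with 7 of 8. Both were at the 100th percentile of random lists matched on expression. Random lists mix unrelated genes, so lists whose genes move together reach such ranks easily. Cholesterol synthesis, goblet cell and mucus, heat shock and mitochondrial lists were at percentile 0 and DNA replication at 99.93, so the percentile singles out no list. Cholesterol synthesis was at -0.25, with 23 of 25 genes below all 3 vehicle libraries, goblet cell and mucus genes at -0.33 and heat shock at -0.20. Heat shock was at -0.28 at both medium and low dose, so it was not lowest at high dose. The mitochondrial transcripts were at -0.25, within the SD of their median among the vehicle libraries, 0.2535. Of 9337 genes measured at 10 CPM or more, 2 were above the vehicle by more than 1, SLC7A11 at 1.34 (273 against 109 ± 17.8 CPM) and AKR1C2 at 1.01. SLC7A11 was at 0.74 at medium and 0.61 at low dose. AKR1C3, AKR1B10, GCLM and CYP1B1 followed at 1.00, 0.99, 0.97 and 0.91. Below the vehicle by more than 1 were 5 genes, the antisense gene CERS6-AS1 at -2.12 (-1.98 already at low dose, with the vehicle at 17.8 ± 8.51 CPM), LINC00261 at -1.11, ATP6V1B1 at -1.07, ACSS2, which makes acetyl-CoA from acetate, at -1.06 and the pseudogene ZBTB45P2 at -1.04.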

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

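The tests of GC content and gene length and of wrong-strand counting below were chosen only after the result was seen, as were the fit without the outlying library and the use of the SD of the marker ratios. Genes named for opposite directions were picked by the size of the difference from genes that both extracts of a pair changed in opposite directions against the vehicle. The difference itself was tested with edgeR's quasi-likelihood test and had to be called. Counted genes also had a symbol and a mean of at least 5 CPM over both groups and the vehicle. XIST and symbols ending in Y were left out. The number of genes called by both extracts in either direction was not counted.

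By these rules, Polygalae Radix and Aucklandiae Radix at high dose moved 342 genes in opposite directions against the vehicle. In 73 of these Polygalae Radix was the higher and in 269 the lower. NR0B2, a nuclear receptor of bile acid control, had 1.06 in Polygalae Radix and -3.87 in Aucklandiae Radix, a difference of 4.93 (log2). CLU, an extracellular chaperone, had -1.53 and 2.62 (difference -4.15), ZNF185, an actin-binding protein, -1.10 and 2.87 (-3.97), and the growth factor PDGFB -0.54 and 3.35 (-3.89). MAOB, which oxidises amines, differed by -3.83 and the kinase anchor AKAP12 by -3.74. Asparagine synthetase ASNS, in the integrated stress response list, had -1.52 and 1.69. Saengmaek-san and Guibi-tang had 2 such genes, the coiled-coil gene CCDC9B (-0.57) and the integrin ITGA3 (-0.51). Menthae Herba and Saposhnikoviae Radix had 0, with 1904 genes at unadjusted p under 0.05 in their direct edgeR comparison. Saengmaek-san and Saposhnikoviae Radix high had only 78 and 53 calls against the vehicle, which limits both numbers.

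Saposhnikoviae Radix low replicate 2 was far from all other libraries. Over 3925 protein-coding genes that overlap no other gene, the SD of its log2 ratios to its group mates was 1.63, against at most 0.311 in other libraries. Wrong-strand counting was taken to leave this SD in the range of the others. It could instead leave such genes only stray reads with varied ratios. Few counts would then remain, and antisense genes would hold a large share of them. The library had 17079221 counts, against 18690501 in the next lowest. Antisense genes took 1.16% of them, above the other libraries but a small share. With the SD, these values argue against wrong-strand counting as the whole cause. After removing a smooth trend in GC content and length the SD was 1.39, against at most 0.297, so these are not the whole cause. Markers of hepatocytes, blood cells and fibroblasts had median log2 ratios of 0.76, 0.453 and 0.124, with SDs over their genes of 1.26, 0.946 and 2.29. Each median is within its SD of the rise of 1 that RNA of another cell type was taken to need. ALB had 0 CPM, COL1A1 0.31, its lowest level of all libraries, and PTPRC 0.0775. Of 18 markers, 9 had their highest level of all libraries here, but that share over all genes was not computed. Among them were APOH at 32.8 CPM and CORO1A at 11.8, whose lowest levels in any library were 15.51 and 3.507 CPM. RNA of another cell type thus stays open. A fault of library preparation or low input may also be the cause and was not tested.

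Without that library, 1354 genes were called at low dose in 4 or more of 7 extracts, 618 higher and 736 lower, with 367 in all 7. With that library there were 12. In 20 simulations in which the extracts share the vehicle the highest such number was 0. They drew genes independently, with 1 spread per gene for all libraries, and called at most 2 genes in any extract. An overlap of 0 was thus nearly fixed and is no yardstick. The vehicle pairs scattered more than most other pairs (chi-square per gene 20.77, 16.87 and 11.11), which the simulations leave out. Of the heat shock list 11 of 18 were among the lower genes, of MAPK output 8 of 18, of metallothioneins 2 of 6, of ER chaperones 5 of 20 and of cell division 6 of 25. Among the higher were 5 of 25 DNA replication genes and 4 of 25 cholesterol genes. Over all 16978 genes tested, 736 were lower and 618 higher. The share of values whose high-minus-medium change kept the sign of the low-minus-vehicle change was 0.456, with extracts from 0.305 to 0.659. That argues against an effect common to the extracts that grows with dose. An offset of the vehicle libraries against all others may be the cause and stays open. The vehicle libraries share no set number with any extract, so the design cannot separate such an offset from an extract effect. Counts against the vehicle thus cannot be read as extract effects alone. The offset would enter high-dose counts too: without that library, Saposhnikoviae Radix, Saengmaek-san and Soyo-san high had 1781, 2047 and 3061 genes against the vehicle and 49, 141 and 441 against low dose. Aucklandiae Radix, Polygalae Radix, Menthae Herba and Guibi-tang had 10627, 6246, 4883 and 5073, and 10030, 5000, 4047 and 3068 against low dose.

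The NRF2 and AHR lists rose in most extracts against the same vehicle libraries. Between high and low dose, which uses no vehicle library, the NRF2 median was above 0.1 in 5 of the 6 extracts in which the list rose, with Saposhnikoviae Radix at 0.06, and at 0.18 without the outlying library. For the NRF2 list these 5 argue against an offset of the shared vehicle libraries as the whole cause, and a response to the extracts that rises with dose is a candidate explanation. The AHR list was not part of this check.

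For comparisons of 3 libraries with 3 there are 10 splits of the 6 libraries, too few for a share under 0.05. The real count and the highest of the other splits were 1071 and 1 for Menthae Herba high, 19 and 1 for its medium dose, 22 and 3 for its low dose, and 936 and 0 for high against low. For Saengmaek-san they were 78 and 2, 38 and 3, 96 and 0, and 6 and 0 in the same order, and for Guibi-tang 1106 and 0, 31 and 1, 13 and 22, and 820 and 0. For Saposhnikoviae Radix they were 53 and 1, 17 and 66, 4721 and 6603, and 4618 and 4548. The direct comparisons had 406 and 0 (Menthae Herba and Saposhnikoviae Radix) and 489 and 0 (Saengmaek-san and Guibi-tang). In Saposhnikoviae Radix medium, 2 of 10 splits gave as many genes, in its low dose 4 of 10, in Guibi-tang low 2 of 10, and in the other comparisons 1, the real one. A split with 66 genes where the real one has 17 points to a structure of those 6 libraries that the groups do not describe, and in both comparisons with the low dose of Saposhnikoviae Radix the outlying library is in 1 of the groups of every split.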

How the results depend on the processing

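The fit without the outlying library was chosen after the data were seen, and all other alternatives before. A count is called stable here if it stays within 1.5 times its first value, and causes were not tested unless said.

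Without the outlying library, 556 of the tests of named genes kept direction and call, and 7 lost the call. All 31 gene counts moved beyond 1.5 times, and the smaller spread estimate (dispersion 0.00272 against 0.0269) shows the cause for those that grew. Against the vehicle the counts were 6246 for Polygalae Radix high, 1763 for Polygalae Radix medium, 1749 for Polygalae Radix low, 10627 for Aucklandiae Radix high, 2358 for Aucklandiae Radix medium, 849 for Aucklandiae Radix low, 4883 for Menthae Herba high, 1783 for Menthae Herba medium, 1640 for Menthae Herba low, 1781 for Saposhnikoviae Radix high, 644 for Saposhnikoviae Radix medium, 1993 for Saposhnikoviae Radix low, 2047 for Saengmaek-san high, 1988 for Saengmaek-san medium, 3124 for Saengmaek-san low, 5073 for Guibi-tang high, 1915 for Guibi-tang medium, 1072 for Guibi-tang low, 3061 for Soyo-san high, 1467 for Soyo-san medium and 1710 for Soyo-san low. Between extracts or doses the counts were 5000 for Polygalae Radix high against low, 10030 for Aucklandiae Radix high against low, 4047 for Menthae Herba high against low, 49 for Saposhnikoviae Radix high against low, 141 for Saengmaek-san high against low, 3068 for Guibi-tang high against low, 441 for Soyo-san high against low, 9952 for Polygalae Radix against Aucklandiae Radix, 2738 for Menthae Herba against Saposhnikoviae Radix and 2156 for Saengmaek-san against Guibi-tang.

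With the DESeq2 Wald test 550 of the tests of named genes kept direction and call and 4 lost the call. The counts beyond 1.5 times were all higher. Against the vehicle the counts were 277 for Polygalae Radix medium, 85 for Polygalae Radix low, 334 for Aucklandiae Radix medium, 25 for Aucklandiae Radix low, 123 for Menthae Herba medium, 102 for Menthae Herba low, 154 for Saposhnikoviae Radix high, 50 for Saposhnikoviae Radix medium, 227 for Saengmaek-san high, 187 for Saengmaek-san medium, 279 for Saengmaek-san low, 153 for Guibi-tang medium, 77 for Guibi-tang low, 405 for Soyo-san high, 95 for Soyo-san medium and 113 for Soyo-san low. Between extracts or doses the counts were 18 for Saengmaek-san high against low and 68 for Soyo-san high against low.

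With no low-count filter 479 tests of named genes kept their call and 84 lost it, with more genes in the adjustment and in the shared spread. No count rose beyond 1.5 times. Against the vehicle the counts were 76 for Polygalae Radix medium, 0 for Polygalae Radix low (edgeR, 1198 genes at unadjusted p under 0.05 with the filter), 90 for Aucklandiae Radix medium, 0 for Aucklandiae Radix low, 619 for Menthae Herba high, 7 for Menthae Herba medium, 9 for Menthae Herba low, 19 for Saposhnikoviae Radix high, 9 for Saposhnikoviae Radix medium, 21 for Saengmaek-san high, 12 for Saengmaek-san medium, 15 for Saengmaek-san low, 713 for Guibi-tang high, 8 for Guibi-tang medium, 7 for Guibi-tang low, 54 for Soyo-san high, 7 for Soyo-san medium and 3 for Soyo-san low. Between extracts or doses the counts were 548 for Menthae Herba high against low, 3 for Saengmaek-san high against low, 14 for Soyo-san high against low, 189 for Menthae Herba against Saposhnikoviae Radix and 325 for Saengmaek-san against Guibi-tang.

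Fitting only the libraries of the extracts compared and the vehicle kept 503 tests of named genes and lost 51. By construction the outlying library is then absent from fits without Saposhnikoviae Radix and a larger part of those with it. Against the vehicle the counts were 4328 for Polygalae Radix high, 366 for Polygalae Radix medium, 19 for Polygalae Radix low, 1331 for Aucklandiae Radix medium, 307 for Aucklandiae Radix low, 4462 for Menthae Herba high, 1640 for Menthae Herba medium, 1424 for Menthae Herba low, 1 for Saposhnikoviae Radix high, 0 for Saposhnikoviae Radix medium, 0 for Saposhnikoviae Radix low, 918 for Saengmaek-san high, 725 for Saengmaek-san medium, 1768 for Saengmaek-san low, 3823 for Guibi-tang high, 886 for Guibi-tang medium, 286 for Guibi-tang low, 1547 for Soyo-san high, 494 for Soyo-san medium and 614 for Soyo-san low. Between extracts or doses the counts were 2991 for Polygalae Radix high against low, 3514 for Menthae Herba high against low, 1 for Saposhnikoviae Radix high against low, 28 for Saengmaek-san high against low, 2023 for Guibi-tang high against low, 60 for Soyo-san high against low, 9325 for Polygalae Radix against Aucklandiae Radix, 56 for Menthae Herba against Saposhnikoviae Radix and 1635 for Saengmaek-san against Guibi-tang.

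With RLE factors 546 tests of named genes kept their call and 17 lost it, and the count moved to 2 for Aucklandiae Radix low and to 10 for Soyo-san medium. With the replicate number as a block 559 kept it and 4 lost it, and the count moved to 9 for Polygalae Radix low, 2 for Aucklandiae Radix low and 38 for Menthae Herba medium. Numbers pair nothing in most groups: no comparison with 3 pairs had a correlation of same-number residuals above 0.1 in every pair, and Soyo-san high, with 2 pairs, had 0.0854 and 0.113.

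Of the 51 list calls, 44 were kept without the outlying library, 39 between high and low dose, 49 by fry, 50 with no low-count filter, 50 with RLE factors, and 51 with the preset correlation and with the block. The number of passing tests was 85 by fry, which does not compare a list with other genes, and 79 with the preset correlation. Between high and low dose the heat shock list turned upward in Saposhnikoviae Radix (adjusted p 0.3517, and 0.271 without the outlying library, upward in both) and Saengmaek-san (0.1156), so neither passed. Leaving out each library in turn kept 1045 list calls and lost 26.

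The similarity of formulas and constituent herbs passed with Spearman correlation (0.2461, exact p 0.0278) and with a minimum of 10 CPM (0.3827, exact p 0.0139), and in the other settings with all libraries its exact p stayed above 0.05. With 1 library left out its mean r ranged from 0.1775 to 0.2227, and it passed without Menthae Herba low replicate 1 (0.2076), Saengmaek-san low replicate 3 (0.204) or Soyo-san high replicate 1 (0.216). For Okbyeongpung-san, 17 of 27 list medians moved beyond the spread of the vehicle medians with its own low-dose library as the reference, and all 27 stayed with a prior count of 0.5 or RLE factors.

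Leaving out each library in turn kept 2522 tests of named genes, lost 517 and turned 4. A group left with 1 library is then assumed to vary like the others. The lowest and highest counts against the vehicle, with the first count in parentheses, were 928 to 1792 for Polygalae Radix high (1937), 55 to 125 for Polygalae Radix medium (144), 0 to 14 for Polygalae Radix low (1), 5182 to 6416 for Aucklandiae Radix high (6886), 34 to 174 for Aucklandiae Radix medium (161), 0 to 1 for Aucklandiae Radix low (1), 665 to 1000 for Menthae Herba high (1071), 3 to 40 for Menthae Herba medium (19), 8 to 25 for Menthae Herba low (22), 12 to 41 for Saposhnikoviae Radix high (53), 5 to 16 for Saposhnikoviae Radix medium (17), 1993 to 8788 for Saposhnikoviae Radix low (4721), 17 to 128 for Saengmaek-san high (78), 7 to 49 for Saengmaek-san medium (38), 11 to 120 for Saengmaek-san low (96), 673 to 953 for Guibi-tang high (1106), 5 to 35 for Guibi-tang medium (31), 2 to 10 for Guibi-tang low (13), 16 to 162 for Soyo-san high (157), 0 to 26 for Soyo-san medium (24) and 0 to 14 for Soyo-san low (12). In the other comparisons they were 767 to 971 for Polygalae Radix high against low (1510), 4707 to 4908 for Polygalae Radix against Aucklandiae Radix (6197), 4850 to 4973 for Aucklandiae Radix high against low (6280), 590 to 674 for Menthae Herba high against low (936), 211 to 272 for Menthae Herba against Saposhnikoviae Radix (406), 49 to 9854 for Saposhnikoviae Radix high against low (4618), 2 to 3 for Saengmaek-san high against low (6), 313 to 404 for Saengmaek-san against Guibi-tang (489), 554 to 654 for Guibi-tang high against low (820) and 2 to 94 for Soyo-san high against low (25). For the lists they were 46 to 55.

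Single libraries moved the counts of medium and low doses beyond 1.5 times. Polygalae Radix low had 14 without Vehicle replicate 1, 0 without Vehicle replicate 2, 0 without Vehicle replicate 3, 14 without its replicate 2 and 0 without its replicate 3. Menthae Herba low had 11 without Vehicle replicate 1, 8 without Vehicle replicate 3, 12 without its replicate 1, 8 without its replicate 2 and 11 without its replicate 3. Guibi-tang medium had 18 without Vehicle replicate 1, 6 without Vehicle replicate 3, 5 without its replicate 1, 5 without its replicate 2 and 6 without its replicate 3. Aucklandiae Radix low had 0 without Vehicle replicate 2, 0 without Vehicle replicate 3, 0 without its replicate 2 and 0 without its replicate 3. Menthae Herba medium had 40 without Vehicle replicate 2, 3 without Vehicle replicate 3, 6 without its replicate 1, 4 without its replicate 2 and 5 without its replicate 3. Guibi-tang low had 5 without Vehicle replicate 2, 2 without Vehicle replicate 3, 8 without its replicate 1, 3 without its replicate 2 and 2 without its replicate 3. Aucklandiae Radix medium had 102 without Vehicle replicate 3, 34 without its replicate 2 and 66 without its replicate 3. Saposhnikoviae Radix medium had 6 without Vehicle replicate 3, 11 without its replicate 1, 7 without its replicate 2 and 5 without its replicate 3. Saengmaek-san medium had 8 without Vehicle replicate 3, 25 without its replicate 1, 9 without its replicate 2 and 7 without its replicate 3. Saengmaek-san low had 11 without Vehicle replicate 3, 11 without its replicate 1, 23 without its replicate 2 and 16 without its replicate 3. Soyo-san medium had 7 without Vehicle replicate 3, 0 without its replicate 1 and 1 without its replicate 2. Soyo-san low had 4 without Vehicle replicate 3, 1 without its replicate 1 and 0 without its replicate 2. Polygalae Radix medium had 59 without its replicate 2 and 55 without its replicate 3. Saposhnikoviae Radix low had 8584 without its replicate 1, 1993 without its replicate 2 and 8788 without its replicate 3. Where a count was 0, edgeR's quasi-likelihood test with all libraries had 1198 genes at unadjusted p under 0.05 for Polygalae Radix low, 835 for Aucklandiae Radix low, 1145 for Soyo-san medium and 1161 for Soyo-san low, and the DESeq2 Wald test called 85, 25, 95 and 113.

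The fall of VIM, a fibroblast marker, against the vehicle rests on Vehicle replicate 1, which has 2.893 CPM against 0.07883 and 0.03666 in the others. Without it the log2 change was 0.05455 in Aucklandiae Radix, 0.3405 in Menthae Herba, 0.3835 in Saposhnikoviae Radix and 0.6659 in Guibi-tang, none of them called. Over all libraries left out in turn the lowest values were -4.664, -4.742, -4.434 and -4.047 in the same order. Vehicle replicate 1 also has FN1 at 4.858 CPM against 2.05 and 1.906, COL5A1 at 0.7368 against 0 in both others, and 24549 genes with at least 1 count, the most of all 60 libraries, and it enters every comparison with the vehicle. Of 60675 genes, 17092 had enough counts for the filter.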

Other observations

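No test in this part was chosen only after its result was seen, except those that leave out the outlying library, and the genes named here were picked after their values were seen. Aucklandiae Radix high had the lowest mean mitochondrial share of counts of all groups, 6.35% ± 0.236 (SD, n = 2), against 11.2% ± 1.53 (n = 3) in the vehicle. Of 13 mitochondrial transcripts 11 fell in it, such as the cytochrome oxidase gene MT-CO3 at -0.97, although the list did not pass (adjusted p 0.4945), and 12 fell adjusted over the list alone. The MAPK feedback phosphatase DUSP5 was at 4.08, the AP-1 subunit FOSL1 at 2.13, the keratin of shed epithelium KRT20 at 1.43 and the gut homeobox gene CDX2 at -2.02 in the same extract, and the dehydrogenase ME1, which supplies NADPH, rose by 1.46.

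The heat shock list fell against the vehicle in Polygalae Radix, Saposhnikoviae Radix and Saengmaek-san. Between high and low dose it was lower in Polygalae Radix (median -0.32, camera adjusted p 0.0401, 0.0646 without the outlying library) and higher in Menthae Herba (0.23, 0.00388).

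In Okbyeongpung-san the AHR list was at 0.61, 0.22 and 0.05 at high, medium and low dose, and the NRF2 list at 0.51, 0.01 and -0.04. Its heat shock median was -0.20, -0.28 and -0.28 in the same order, and its DNA replication median 0.15, 0.13 and 0.11. Library pairs within groups had a chi-square per gene of at least 2.02, so no library was a copy of a group mate.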
